A study of Mus musculus with 18 samples.

How the data were processed

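Gene expression was measured in thyroids of 18 C57BL/6 mice at 1 month of age on single-colour Agilent mouse arrays with 45018 features each. The series groups them as 5 wild-type (WT) and 5 Glis3KO2 (KO2) mice on a normal diet and 4 WT and 4 KO2 mice kept for 6 days on a low-iodine diet, and each array was placed in its group from its title. Per the labels' protocols, mice were weaned at 3 weeks onto an NIH31 or a low-iodine (Harlan) diet, RNA was extracted with an Ambion micro kit, 50 ng of total RNA was amplified with a NuGEN Ovation Pico kit, and Cy3 was attached to 5 ug of the product. Neither the sex of the mice nor the deleted part of Glis3 is given in the sources used here.

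Per the submitters' processing notes, the scans were read with Agilent Feature Extraction version 12. Per the file headers, the 10 normal-diet arrays were scanned on a G2505C and read with release 12.0.0.7, and the 8 low-iodine arrays were scanned on a G2600D and read with release 12.0.3.1. The deposited value used for each spot is its processed signal, a background-subtracted intensity on a linear scale. The deposited summary table held the same processed signal intensity on every array (ratio 1 to the scanner file), with no further scaling or centring. It entered as an alternative, as log2 of the deposited values without scaling.

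The normal-diet arrays lie on slides 1, 2 and 3 and the low-iodine arrays on slides 4 and 5, so diet and array set cannot be told apart. Every slide held both genotypes in equal numbers: 1 and 1 on slide 1, and 2 and 2 on each of the others. Fold changes between genotypes with slide as a block therefore equal the unblocked ones, and the block changes only their errors and p-values. The replicate numbers of WT and KO2 carry no stated pairing and were not used as one.

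For each array, log2 of the processed signal was taken and the array's 75th percentile subtracted, after control spots and spots carrying an outlier flag were removed. Spots of 1 probe were averaged, and 82 probes with every spot flagged on some array were left out. No spot was saturated on any array. Of 41174 probes on the array, 28223 (68.5%) were matched through their accession to 1 gene of the GRCm38.p6 gene table, 0 to several genes and 12951 to none. Coordinates were not used. Probes well above background on at least 4 of the 18 arrays were kept, which left 26519 probes with a gene name, and the brightest probe stood for each of 17929 genes. Where a gene was not well above background on any array of a group, its difference is given as a bound ("at least"), the brighter group's mean against the dimmer group's mean of the higher of its own value and the lowest signal of probes well above background. Members of gene families with near-identical copies (the Dcpp and Klk1b genes, Hamp2 and Stfa2) are uncertain, since a probe can read more than 1 of them.

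One limma model (lmFit, contrasts.fit and eBayes, limma 3.58.1 in R 4.3.3) was fitted to the 4 group means over all 18 arrays, which share 1 estimate of each gene's spread. Its contrasts were KO2 against WT on each diet, the difference between these (the genotype by diet interaction), and low-iodine against normal diet in each genotype. P-values were adjusted over genes with the Benjamini-Hochberg method, and an adjusted p under 0.05 is the threshold throughout. Fold changes are given on the log2 scale as KO2 minus WT, with the standard error (SE) of the fit. The genes named in the text were chosen by rules fixed before the data were examined: Glis3, every measured thyroid hormone synthesis gene, the 8 largest changes of each sign whose arrays did not overlap between the groups (6 for the interaction, without the condition on overlap), and up to 4 members with the smallest p of each pathway list with a call. In picking the largest changes, genes not well above background on any array of a compared group were skipped. Clone, predicted-gene and accession-like names were skipped too. Wherever the text calls changes the largest, or says that genes rose or fell most, it ranks only the genes left. Members of the marker lists and of the added lists (such as Krt5, Dcn, Calca and Psmb11), Ndrg2 and Bub1 were named after their values were seen, and the alternatives were not run for these genes singly. Results for some single genes are not reported here.

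In the same way, 16 pathway lists and 21 lists of cell type and sex markers were fixed. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the pathway lists or over the marker lists of a contrast, and calls of single members were also adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. The pathway lists cover thyroid hormone synthesis, thyroid lineage transcription factors, mitosis, DNA replication, extracellular matrix and fibrosis, inflammation and chemokines, cAMP and immediate early response, endoplasmic reticulum stress and protein folding, angiogenesis, primary cilium, antioxidant response, cholesterol synthesis, lysosome, glycolysis and hypoxia, amino acid transport and mTORC1, and oxidative phosphorylation. Lists for thymic epithelium and for genes that escape X inactivation were added after the data were examined.

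Other alternatives were quantile normalization, median scaling, normexp background correction (offset 50) on the median spot and background signals, no filter or a stricter filter on dim probes, the mean of a gene's probes, eBayes with trend and robust settings, array weights, a Y-linked score as covariate, slide or replicate number as a block, only the arrays of 1 diet (for gene counts), a 2-fold minimum, and leaving out each array in turn. Fits with muscle or thymus marker scores as covariates, fits without 2 arrays carrying thymocyte genes, and fits with only the arrays of 1 diet for lists and named genes were added after the data were examined.

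The code was tested on simulated values for the 17929 genes, built on the spread of the real arrays, with 200 genes changed by 1 or 2 on the log2 scale. On the normal diet 60% of the smaller and 88% of the larger changes were recovered, with 12 of 17685 unchanged genes called. On the low-iodine diet these shares were 34% and 81%, with 2 unchanged genes called, and for the interaction 11% and 62%, with 2. The simulated noise was independent between genes, with no slide effect, no RNA of other tissues and no outlying arrays. These rates therefore test the code and may not hold for the real arrays. Probes without a gene name (9806 tested) were left out of the comparisons and are counted among the additional observations.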

Results

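The arrays report thyroid gene expression in WT mice and in Glis3KO2 mice, in which the gene for the zinc finger transcription factor Glis3 is targeted. Thyroids came from 5 mice of each genotype on a normal diet and from 4 of each after 6 days on a low-iodine diet. That diet withholds the substrate of thyroid hormone and in normal animals raises thyrotropin (TSH). The design asks which thyroid genes depend on Glis3 on a normal diet and which when the gland is called upon to respond to low iodine. Between 60.1% and 90.6% of spots were well above background on an array, and median signals ran from 45.0 to 191.5. The number of arrays limits the precision of every value. Correlations between arrays of the same group ran from 0.944 to 0.988 and between arrays of different diets from 0.73 to 0.83.

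Glis3 itself was read by 1 probe. On the normal diet its log2 level relative to the array's 75th percentile was −5.01, −4.78, −6.08, −5.04 and −5.77 in WT replicates 1 to 5 and −5.46, −4.16, −4.43, −4.96 and −5.46 in KO2 replicates 1 to 5. In each group 4 of 5 arrays were well above background. KO2 differed from WT by 0.45 ± 0.42 (SE, adjusted p = 0.736). On the low-iodine diet it was −1.60, −1.31, −1.32 and −0.74 in WT replicates 1 to 4 and −4.06, −1.49, −1.91 and −2.93 in KO2 replicates 1 to 4. This is a difference of −1.36 ± 0.47 (SE) with an adjusted p of 0.0620, or 0.0260 with slide as a block (0.0212 to 0.201 over 24 alternatives). The probe may lie outside the deleted part of the gene, in which case its level checks nothing about the labels.

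On the normal diet, the clearest difference between the genotypes was in genes of cell division, which were lower in KO2 thyroids. Mki67, the standard marker of proliferating cells, was 10.1-fold lower in KO2 (log2 fold change −3.34 ± 0.54 SE, n = 5 and 5, adjusted p = 0.00731). Ncapg, a condensin subunit that compacts mitotic chromosomes, was 11.1-fold lower (−3.47 ± 0.59 SE, adjusted p = 0.00938), and Nuf2, part of the kinetochore, was 7.66-fold lower (−2.94 ± 0.42 SE, adjusted p = 0.00360). Of the thyroid's iodide genes, Slc26a4, which encodes the anion exchanger pendrin of the apical membrane, fell 5.58-fold (−2.48 ± 0.35 SE, adjusted p = 0.00360). Over 24 alternatives the log2 fold change ran from −2.73 to −1.03 for Slc26a4, −3.32 to −1.30 for Nuf2 and −4.04 to −1.97 for Ncapg. Slc5a5, the sodium/iodide symporter, did not pass the threshold (−0.55 ± 0.39 SE, adjusted p = 0.620). In all, 253 of 17929 genes passed the threshold, 92 higher and 161 lower in KO2 (63.6% lower, against 73.7% with median scaling and 90.6% of the calls without scaling). Of these, 188 differed at least 2-fold.

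The mitosis list had a median log2 fold change of −2.44, with 30 of its 44 measured members lower in KO2 and 0 higher (39 lower when adjusted over the list alone; list test adjusted p = 7.86e-51). With genes below background at their bound the median was −2.31. The adjusted p was 0.0301 with an estimated correlation and 2.76e-42 with slide as a block. Within slides 1, 2 and 3 the median was −2.53, −1.65 and −3.01. The mean level of the list in KO2 replicate 4 (−2.86) lay within the WT range of −2.98 to −0.39, in which WT replicate 5 stood highest. The other KO2 arrays lay below that range. Cenpf fell by 4.76 ± 0.76 (SE), Cdca3 by 3.03 ± 0.48 (SE), and the spindle motor Kif11, not well above background on any KO2 array, was at least 2.14-fold lower. The proliferation genes Shcbp1 (−3.07 ± 0.46 SE) and Pclaf (−3.16 ± 0.59 SE) and the repressor Mxd3 (−3.19 ± 0.58 SE), none of them in a list, were lower as well. Over 24 alternatives Mxd3 ran from −3.61 to −0.97 and Shcbp1 from −3.41 to −1.47. Among 42 measured DNA replication genes, 6 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of −0.44 and medians of −0.40, −0.24 and −0.65 within the slides. They included the cell cycle transcription factor E2f1 (−1.94 ± 0.34 SE), the checkpoint kinase Chek1 (−2.22 ± 0.41 SE), the thymidine kinase Tk1 (−1.41 ± 0.28 SE) and the exonuclease Exo1 (−2.16 ± 0.44 SE, adjusted p = 0.0210). Chek1 and Tk1 were above 0.05 in 3 of 24 alternatives each. Cenpf and Chek1 were well above background on 1 of 5 KO2 arrays, so their differences rest on dim values. The replication list passed its test (adjusted p = 3.51e-13, 8.74e-12 with slide as a block). The call was lost with an estimated correlation (adjusted p = 0.154 with an estimated correlation).

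Thymus markers were lower in KO2 too, on average. The mean log2 level of 7 thymic epithelium genes was −1.43 ± 2.02 (SD, n = 5) in WT and −4.30 ± 1.43 (SD, n = 5) in KO2 on the normal diet. WT replicate 1 (−4.68) was among the low arrays and KO2 replicate 2 (−1.81) among the high ones. The thymus and T cell list had a median of −1.71 in KO2 against WT (adjusted p = 0.0185, and 0.642 with an estimated correlation). Its call was lost without WT replicate 5 (median −0.20, adjusted p = 0.345), KO2 replicate 4 (0.0619) or KO2 replicate 5 (0.0785), and ran from 9.59e-04 to 0.696 over the alternatives. Skeletal muscle markers had a median of 2.17 (adjusted p = 0.0192, and 0.796 with an estimated correlation). The call was lost without WT replicate 1 (0.117) or 4 (median 1.44, 0.286) and without KO2 replicate 1 (0.113), 2 (0.111) or 4 (median 1.29, 0.263). Without KO2 replicate 3 the median was 3.78 (adjusted p = 6.93e-07). They varied between arrays of 1 group, with means of −0.17 ± 2.92 (SD, n = 5) in WT and 1.99 ± 4.00 (SD, n = 5) in KO2. The airway epithelium list (median −0.94, adjusted p = 0.0167, and 0.335 with an estimated correlation), the parathyroid list (−0.89, adjusted p = 0.0185, and 0.642) and the squamous and basal epithelium list (−0.38, adjusted p = 0.0185, and 0.145) were lower. The parathyroid call rests on KO2 replicate 3, without which the median was −0.40 (adjusted p = 0.203), and was lost without WT replicate 4 (0.0501; 4.38e-04 to 0.642 over the alternatives). The squamous call was lost without KO2 replicate 4 (0.0806; 0.00747 to 0.147). In this list the basal keratins Krt5 (−2.75 ± 0.64 SE) and Krt14 (−1.52 ± 0.29 SE) fell.

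Genes of the extracellular matrix were lower in KO2 on the normal diet. Of 30 measured members 3 fell and 0 rose (8 lower and 1 higher adjusted over the list alone). The median was −0.38, with medians of −0.29, −0.46 and −0.32 within slides 1, 2 and 3. These were the fibrillar collagens Col1a1 (−1.82 ± 0.40 SE, adjusted p = 0.0310), Col1a2 (−1.21 ± 0.25 SE, adjusted p = 0.0190) and Col3a1 (−2.14 ± 0.44 SE, adjusted p = 0.0213), which were above 0.05 in 8, 2 and 5 of 24 alternatives. The list passed its test (adjusted p = 1.94e-07, 2.09e-07 with slide as a block, and 0.0301 with an estimated correlation). The fibroblast marker list was lower beside it, with a median of −0.93 (adjusted p = 5.89e-05, and 0.145 with an estimated correlation). Col14a1 (−1.75 ± 0.37 SE) was its 1 call.

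Of 16 measured thyroid hormone synthesis genes, 1 rose, Slc26a4 fell and 14 did not pass (2 higher and 2 lower adjusted over the list alone). The list test gave an adjusted p of 0.556, with a median of 0.04, a mean of −0.12 and a downward test direction. Tg, the thyroglobulin gene, differed by 0.07 ± 0.17 (SE, adjusted p = 0.913). The thyrotropin receptor Tshr differed by 1.33 ± 0.32 (SE, adjusted p = 0.0519, or 0.0246 with slide as a block, and 0.0189 to 0.178 over 24 alternatives). Within slides 1, 2 and 3, Slc26a4 differed by −3.50, −2.36 and −2.10. Ano1, Dio1, Dio2, Duox1, Duoxa2, Iyd, Kcne2, Kcnq1, Slc16a10, Slc5a5 and Slc5a8 lay between −0.75 and 0.40. The 3 probes of Slc16a10 disagreed in sign, at −0.75, 1.22 and 0.11. Nkx2-1, a transcription factor of the thyroid lineage, was higher by 0.61 ± 0.14 (SE, adjusted p = 0.0368). It was the only call among 11 measured lineage factors, whose list did not pass (3 higher and 1 lower adjusted over the list alone, median 0.09, adjusted p = 0.484). The follicular cell markers, which include Nkx2-1, had a median of 0.68, with 2 of 6 higher (adjusted p = 2.65e-04, and 0.108 with an estimated correlation).

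Among genes whose arrays did not overlap between the genotypes, those that rose most in KO2 on the normal diet were S100a5, a calcium-binding protein gene (3.08 ± 0.70 SE, adjusted p = 0.0386), and Sdr16c6, a short-chain dehydrogenase gene (3.03 ± 0.30 SE, adjusted p = 2.80e-04). Next came Atp6v1c2, a subunit of the proton pump (2.76 ± 0.28 SE, adjusted p = 2.80e-04), and Grp, gastrin-releasing peptide (2.53 ± 0.31 SE, adjusted p = 0.00171). Wfikkn2, a secreted protease inhibitor gene (2.50 ± 0.44 SE), the channel subunit gene Kcne1 (2.14 ± 0.37 SE) and the coagulation factor gene F10 (1.97 ± 0.29 SE) followed. S100a5 was above 0.05 in 13 of 24 alternatives (0.0128 to 0.148). Of the genes without overlap outside cell division, the tissue kallikreins Klk1b9 (−3.58 ± 0.61 SE) and Klk1b24 (−3.33 ± 0.64 SE) and Clca1 (−3.28 ± 0.76 SE, adjusted p = 0.0419) fell most. Kallikrein probes can read more than 1 member of their family.

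The cAMP and immediate early response list was higher (median 0.29, adjusted p = 0.00114, and 0.107 with an estimated correlation). Of its 24 measured members the phosphatase Dusp1 rose (1.63 ± 0.30 SE) and 23 did not pass. The glycolysis and hypoxia list (median 0.26, adjusted p = 0.00283, and 0.154 with an estimated correlation) was higher. Bnip3, a mitophagy receptor induced in hypoxia, rose by 0.91 ± 0.20 (SE, adjusted p = 0.0357). The oxidative phosphorylation list was higher (0.17, adjusted p = 0.0120, and 0.659 with an estimated correlation), with 0 members past the threshold. The endoplasmic reticulum stress and protein folding list was lower (−0.41, adjusted p = 0.0120, and 0.659 with an estimated correlation), also with 0 members past it. Within slides 1, 2 and 3 the medians were 0.27, 0.13 and 0.60 for cAMP, 0.75, 0.25 and 0.03 for glycolysis. They were 0.50, 0.26 and −0.13 for oxidative phosphorylation, and −0.86, 0.05 and −0.37 for endoplasmic reticulum stress. The endoplasmic reticulum list lost its call without WT replicate 1 (median −0.05, adjusted p = 0.769), WT replicate 5 (0.470) or KO2 replicate 4 (0.309), and ran from 1.19e-07 to 0.769 over the alternatives. Oxidative phosphorylation lost its call without KO2 replicate 2 (0.126) or KO2 replicate 4 (0.300), and ran from 3.14e-06 to 0.659. Glycolysis lost it without KO2 replicate 4 (0.0527), and ran from 1.28e-04 to 0.154. The lysosome list did not pass (−0.13, adjusted p = 0.158), though Npc2, a cholesterol carrier of the lysosome, rose by 0.71 ± 0.17 (SE, adjusted p = 0.0470). Angiogenesis (−0.18, adjusted p = 0.0683), inflammation and chemokines (−0.05, adjusted p = 0.484), cholesterol synthesis (−0.09, adjusted p = 0.484), primary cilium (0.05, adjusted p = 0.800), antioxidant response (0.20, adjusted p = 0.131) and amino acid transport and mTORC1 (−0.13, adjusted p = 0.372) did not pass.

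With slide as a block 196 genes passed, and 248 of the 253 calls had the same direction on all 3 slides. Of the named genes, the block took Nkx2-1 (adjusted p = 0.0670, and 0.0224 to 0.316 over 24 alternatives), Exo1 (0.0522, and 0.0108 to 0.118) and Clca1 (0.0581, and 0.00365 to 0.209) past 0.05. It did the same to Bnip3 (0.0552, and 0.0113 to 0.197) and Npc2 (0.0612, and 0.0187 to 0.197). Over the 24 alternatives the call was lost in 18 for Clca1, 17 for Npc2, 14 for Nkx2-1, 13 for Bnip3 and 9 for Exo1. The normal-diet count changed strongly with the arrays that entered the fit. A fit of these 10 arrays alone called 3 genes: Sdr16c6, Atp6v1c2 and the stress-responsive Ndrg2 (1.66 ± 0.20 SE in that fit), which is named after its value was seen because the count is so small. Fold changes are the same in that fit, and all 253 calls had an unadjusted limma p under 0.05 in it. The count was 156 without WT replicate 2, 145 without WT replicate 5, and 160, 124, 679 and 141 without KO2 replicates 1, 3, 4 and 5. The thymus and T cell score or the thymic epithelium score as a covariate left 78 or 15.

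**Figure D1:**
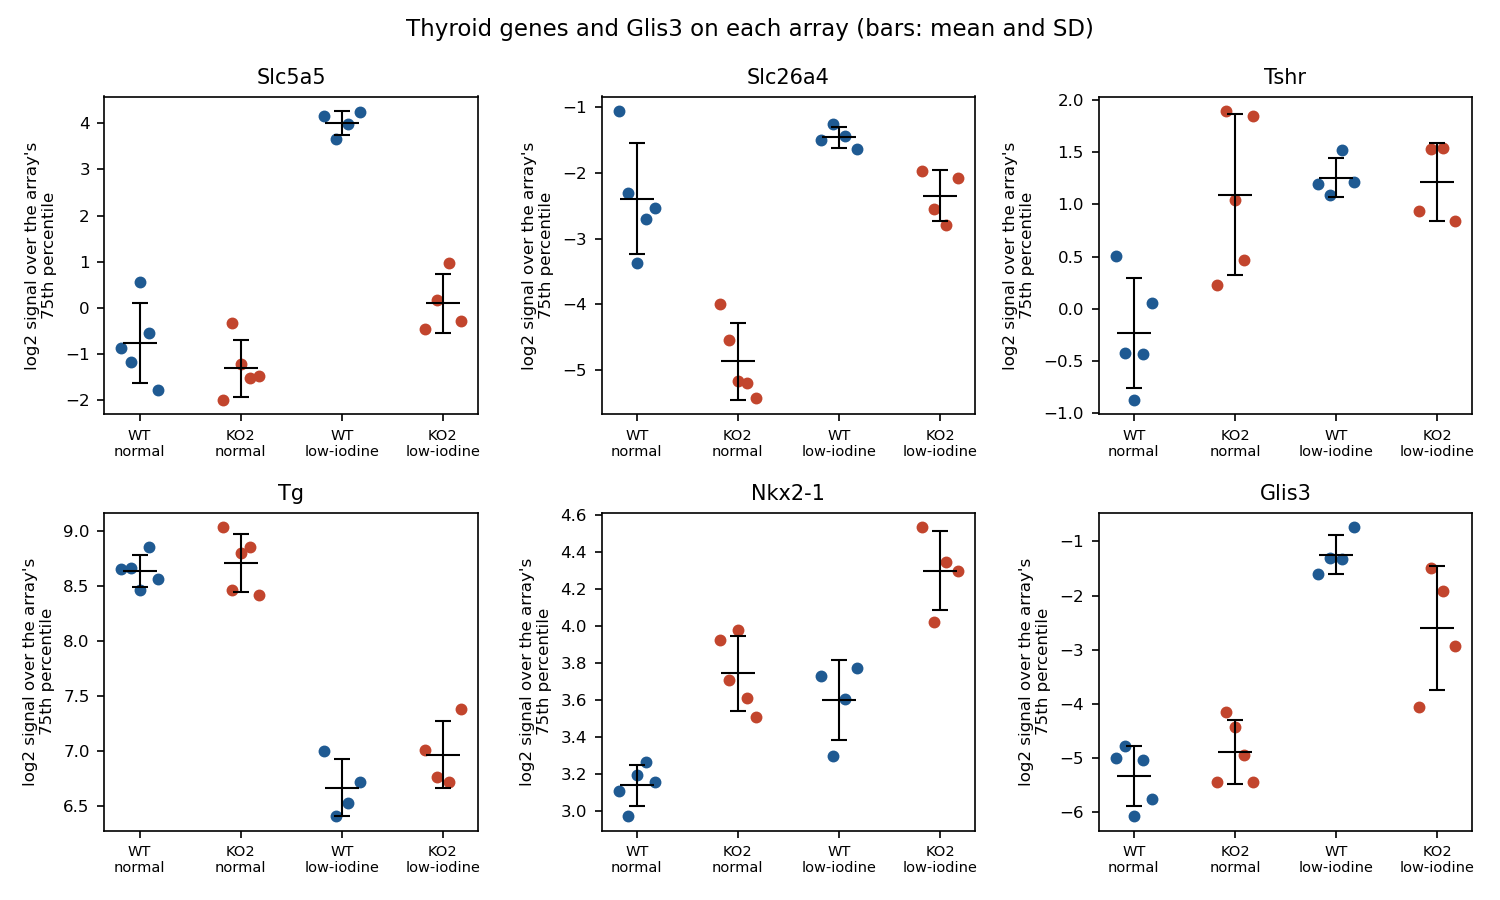
Log2 signal relative to the array's 75th percentile (vertical axis) of Slc5a5, Slc26a4, Tshr, Tg, Nkx2-1 and Glis3 on each array, by genotype and diet. Points are mice and bars are the mean and SD of 5 or 4 mice. Slc5a5 lay at 4.01 in WT and 0.10 in KO2 on the low-iodine diet, and Slc26a4 at −2.39 in WT and −4.87 in KO2 on the normal diet.

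On the low-iodine diet the sodium/iodide symporter gene Slc5a5, which brings iodide into the follicular cell, was 15.1-fold lower in KO2 thyroids (−3.92 ± 0.44 SE, n = 4 and 4, adjusted p = 2.70e-05). Its log2 level was 4.01 ± 0.26 (SD, n = 4) in WT and 0.10 ± 0.64 (SD, n = 4) in KO2, and within slides 4 and 5 it differed by −4.28 and −3.55. Cell division genes were far lower. Cep55, needed for the final separation of daughter cells, was well above background on 1 of 4 KO2 arrays, and the fitted difference of 148-fold (−7.21 ± 0.64 SE, adjusted p = 5.25e-06) ran from −8.42 to −3.92 (log2) over 24 alternatives. Top2a, the topoisomerase of dividing cells, fell 54.3-fold (−5.76 ± 0.58 SE, adjusted p = 1.20e-05). Genes of the extracellular matrix fell with them, among them the collagen Col1a1, 15.1-fold (−3.91 ± 0.45 SE, adjusted p = 3.36e-05). Altogether 2683 of 17929 genes passed the threshold, 1399 higher and 1284 lower (47.9% lower, against 86.5% of the calls without scaling and 57.6% with the arrays of this diet alone). Of these, 434 and 887 differed at least 2-fold.

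Of 44 measured mitosis genes 42 were lower in KO2 and 0 higher (44 adjusted over the list alone). The median was −4.07, with −3.92 and −4.21 within slides 4 and 5 (list adjusted p = 8.80e-47, 2.34e-39 with slide as a block, and 0.0400 with an estimated correlation). Nuf2 (−5.19 ± 0.46 SE), the cytokinesis regulator Ect2 (−4.19 ± 0.38 SE), the centrosome kinase Nek2 (−6.05 ± 0.75 SE) and Ccnb1, cyclin B1 (−5.59 ± 0.87 SE), were lower. The kinase Melk, not well above background on any KO2 array, was at least 52.7-fold lower. Iqgap3, a scaffold protein gene of proliferating cells, fell by 6.30 ± 0.72 (SE). Ccnb1 and Iqgap3 were well above background on 1 of 4 KO2 arrays, as was E2f8, so their differences rest on dim values. Of 42 measured DNA replication genes 30 fell and 0 rose (35 adjusted over the list alone). The median was −1.32, with −0.93 and −1.56 within the slides. Tk1 (−3.69 ± 0.31 SE), E2f1 (−3.53 ± 0.38 SE) and E2f8 (−3.91 ± 0.47 SE) were among those with the smallest p. This list passed its test (adjusted p = 9.79e-23, and 2.08e-20 with slide as a block), with adjusted p = 0.0545 with an estimated correlation. The thymus and T cell list did not differ past its test on this diet (median −0.01, adjusted p = 0.832). The thymic epithelium mean was −2.57 ± 0.54 (SD, n = 4) in WT and −2.93 ± 0.34 (SD, n = 4) in KO2.

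Of 30 measured matrix genes 22 fell and 0 rose (26 adjusted over the list alone). The median was −2.05, with −1.96 and −1.79 within slides 4 and 5 (list adjusted p = 2.33e-22, 1.03e-20 with slide as a block, and 1.86e-04 with an estimated correlation). Sparc, a collagen-binding glycoprotein gene, fell by 1.96 ± 0.20 (SE), the proteoglycan Bgn by 2.16 ± 0.24 (SE) and the basement membrane collagen Col4a1 by 2.07 ± 0.23 (SE). The fibroblast markers moved in both directions beside them (median −1.17, list adjusted p = 0.0771), with Mfap5 (−2.18 ± 0.25 SE), Col14a1 (−2.70 ± 0.41 SE) and Pi16 (−2.38 ± 0.54 SE) lower and Dcn higher (0.99 ± 0.23 SE). The angiogenesis list fell too, with 9 of 21 measured members lower and 0 higher (11 adjusted over the list alone). Its median was −0.61, with −0.55 and −0.70 within the slides (adjusted p = 2.14e-04, 4.73e-04 with slide as a block, and 0.198 with an estimated correlation). Its calls included the endothelial peptide Apln (−2.86 ± 0.31 SE), the angiopoietin receptor Tek (−1.33 ± 0.20 SE), the vessel guidance receptor Unc5b (−2.17 ± 0.33 SE) and Nrp2 (−0.86 ± 0.20 SE). Endothelial markers were lower beside it (5 of 10 past the threshold, median −0.65, adjusted p = 0.00814, and 0.863 with an estimated correlation). Among them was Cdh5, VE-cadherin (−1.47 ± 0.23 SE). The pericyte and smooth muscle list did not pass (median −0.58, adjusted p = 0.0720). Cartilage markers had a median of −0.64 (4 of 9 lower, adjusted p = 0.00814, and 0.476 with an estimated correlation), or −0.38 without WT replicate 2 (adjusted p = 0.0291).

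Of the 16 measured thyroid hormone synthesis genes, 3 fell, Slc5a5 and Iyd among them, and Slc5a8 rose (6 lower and 1 higher adjusted over the list alone). The list median was −0.51, with −0.58 and −0.60 within slides 4 and 5 (adjusted p = 0.00981, 0.00648 with slide as a block, and adjusted p = 0.0545 with an estimated correlation). Iyd, which recovers iodide from iodotyrosines, differed by −0.72 ± 0.22 (SE, adjusted p = 0.0398, above 0.05 in 7 of 24 alternatives). Slc5a8, a monocarboxylate transporter of the apical membrane, was higher by 0.87 ± 0.26 (SE, adjusted p = 0.0307, above 0.05 in 8 of 24 alternatives). Slc26a4 differed by −0.89 ± 0.39 (SE, adjusted p = 0.145), Tg by 0.30 ± 0.18 (SE, adjusted p = 0.327). Tshr differed by −0.04 ± 0.36 (SE, adjusted p = 0.958). Ano1, Dio1, Dio2, Duox1, Duoxa2, Kcne2, Kcnq1 and Slc16a10 lay between −2.47 (Dio2, adjusted p = 0.0746) and −0.24 (Duox1) and did not pass. The probes of Slc16a10 again disagreed in sign. Among 11 thyroid lineage factors Isl1 (1.10 ± 0.18 SE, adjusted p = 8.00e-04) and Nkx2-1 (0.70 ± 0.15 SE, adjusted p = 0.00550) rose (2 adjusted over the list alone; list median 0.02, adjusted p = 0.276). Follicular cell markers had a median of 0.20 (adjusted p = 0.302). C cell markers were higher (median 0.57, adjusted p = 0.0257, and 0.476 with an estimated correlation), a call lost without WT replicate 1 (0.0681) or KO2 replicate 3 (0.0611; 0.00576 to 0.476 over the alternatives), with Calca, the calcitonin gene, at 1.20 ± 0.19 (SE) and Chgb, chromogranin B, at 1.42 ± 0.23 (SE).

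Cholesterol synthesis genes were lower, 10 of 21 past the threshold and 0 higher (11 adjusted over the list alone). The median was −0.52, with −0.64 and −0.66 within slides 4 and 5 (adjusted p = 1.29e-05, 2.36e-05 with slide as a block, and adjusted p = 0.0603 with an estimated correlation). They included the sterol carrier Stard4 (−1.55 ± 0.29 SE), Sc5d (−0.98 ± 0.19 SE) and Dhcr7 (−1.25 ± 0.25 SE). The inflammation and chemokine list fell, with 4 of 30 members lower (4 adjusted over the list alone) and a median of −0.46, or −0.38 and −0.31 within the slides. Its adjusted p was 0.0164 (0.0129 with slide as a block, 0.473 with an estimated correlation, 0.0631 without KO2 replicate 3, and 0.00569 to 0.473 over the alternatives). Its calls included the chemokine Ccl4 (−2.53 ± 0.47 SE), the chemokine receptor Ccr2 (−1.25 ± 0.38 SE, above 0.05 in 7 of 24 alternatives) and the cytokine Il6, not well above background on any KO2 array and at least 2.78-fold lower. Macrophage markers had a median of −0.60 (adjusted p = 0.176). The neutrophil markers S100a8 (2.77 ± 0.71 SE) and S100a9 (2.63 ± 0.39 SE) were higher, in a list with a median of −0.21 (adjusted p = 0.302).

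Lists without a list call still held single calls. Of the cAMP list (median 0.25, adjusted p = 0.425), Rgs2 (1.19 ± 0.25 SE) and Egr1 (1.41 ± 0.42 SE) were higher and Pde4b (−1.36 ± 0.20 SE) and Egr3 (−1.32 ± 0.42 SE) lower. Of the primary cilium list (median 0.20, adjusted p = 0.179), 4 members were higher, among them Bbs2 (0.94 ± 0.28 SE), Bbs4 (0.67 ± 0.18 SE) and Ift140 (0.66 ± 0.16 SE), and 1 was lower. The antioxidant list (0.17, adjusted p = 0.271) held the plasma glutathione peroxidase Gpx3 (1.73 ± 0.35 SE) and the regulator Nfe2l2 (0.82 ± 0.17 SE) as higher and Gpx2 (−0.998 ± 0.26 SE) as lower. The lysosome list (−0.18, adjusted p = 0.0676, or 0.0456 with slide as a block) held the hydrolases Hexa (−1.52 ± 0.26 SE), Ctsa (−0.80 ± 0.23 SE) and Asah1 (−0.64 ± 0.19 SE) among 4 lower genes, and 1 higher gene. In glycolysis and hypoxia (0.05, adjusted p = 0.474), Bnip3 (0.98 ± 0.23 SE), Ndrg1 (1.03 ± 0.30 SE) and Adm (0.72 ± 0.24 SE) rose and Pgk1 fell (−0.58 ± 0.18 SE). In amino acid transport and mTORC1 (0.01, adjusted p = 0.271), the receptor Igf1r (0.86 ± 0.18 SE), Slc1a5 (0.79 ± 0.20 SE) and Rps6kb1 (0.57 ± 0.16 SE) rose and the growth factor Igf1 fell (−0.97 ± 0.24 SE). Ern1, a sensor of unfolded protein, rose (1.19 ± 0.20 SE) in a list with a median of −0.57 (adjusted p = 0.231). Oxidative phosphorylation had 0 calls (0.12, adjusted p = 0.271). Several of these single calls were above 0.05 in many of 24 alternatives: Adm in 18 (0.0208 to 0.450), Egr3 in 11 (0.0253 to 0.129), Pgk1 in 9 (0.00152 to 0.101) and Ndrg1 in 8 (0.00266 to 0.199). For Bbs2 and Asah1 it was 7 each, for Egr1 6, for Ctsa 5, and for Bbs4 and Rps6kb1 4 each.

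Among genes whose arrays did not overlap, those that rose most in KO2 on the low-iodine diet were the cytochrome P450 gene Cyp2b9 (5.36 ± 1.40 SE, adjusted p = 0.0162), the methyltransferase gene Inmt (5.33 ± 0.40 SE, adjusted p = 1.53e-06) and the hepcidin gene Hamp2 (4.95 ± 0.89 SE). S100a5 (4.09 ± 0.78 SE), the lipocalin Apod (3.24 ± 0.37 SE), the stefin Stfa2 (3.12 ± 0.69 SE), the protease inhibitor Slpi (2.99 ± 0.42 SE) and the melanocortin receptor Mc4r (2.98 ± 0.33 SE) followed. Cyp2b9 was well above background on 1 of 4 WT arrays and lost its call with normexp background correction (1.45, adjusted p = 0.239, and 5.81e-04 to 0.239 over 24 alternatives). Of the genes without overlap outside cell division, Dcpp2 (−6.06 ± 0.93 SE) and Dcpp1 (−5.63 ± 0.97 SE), genes of saliva proteins that a probe cannot fully tell apart, and the metalloproteinase Adamts8 (−5.88 ± 0.50 SE) fell most. With slide as a block 2894 genes passed, and 2682 of the 2683 calls had the same direction on both slides. A fit of these 8 arrays alone called 1676 genes and median scaling gave 1635. All 4 Y-linked genes were well above background on WT replicates 1 and 2 and KO2 replicates 1, 2 and 3, so the genotypes differed in their number of such samples.

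**Figure D2:**
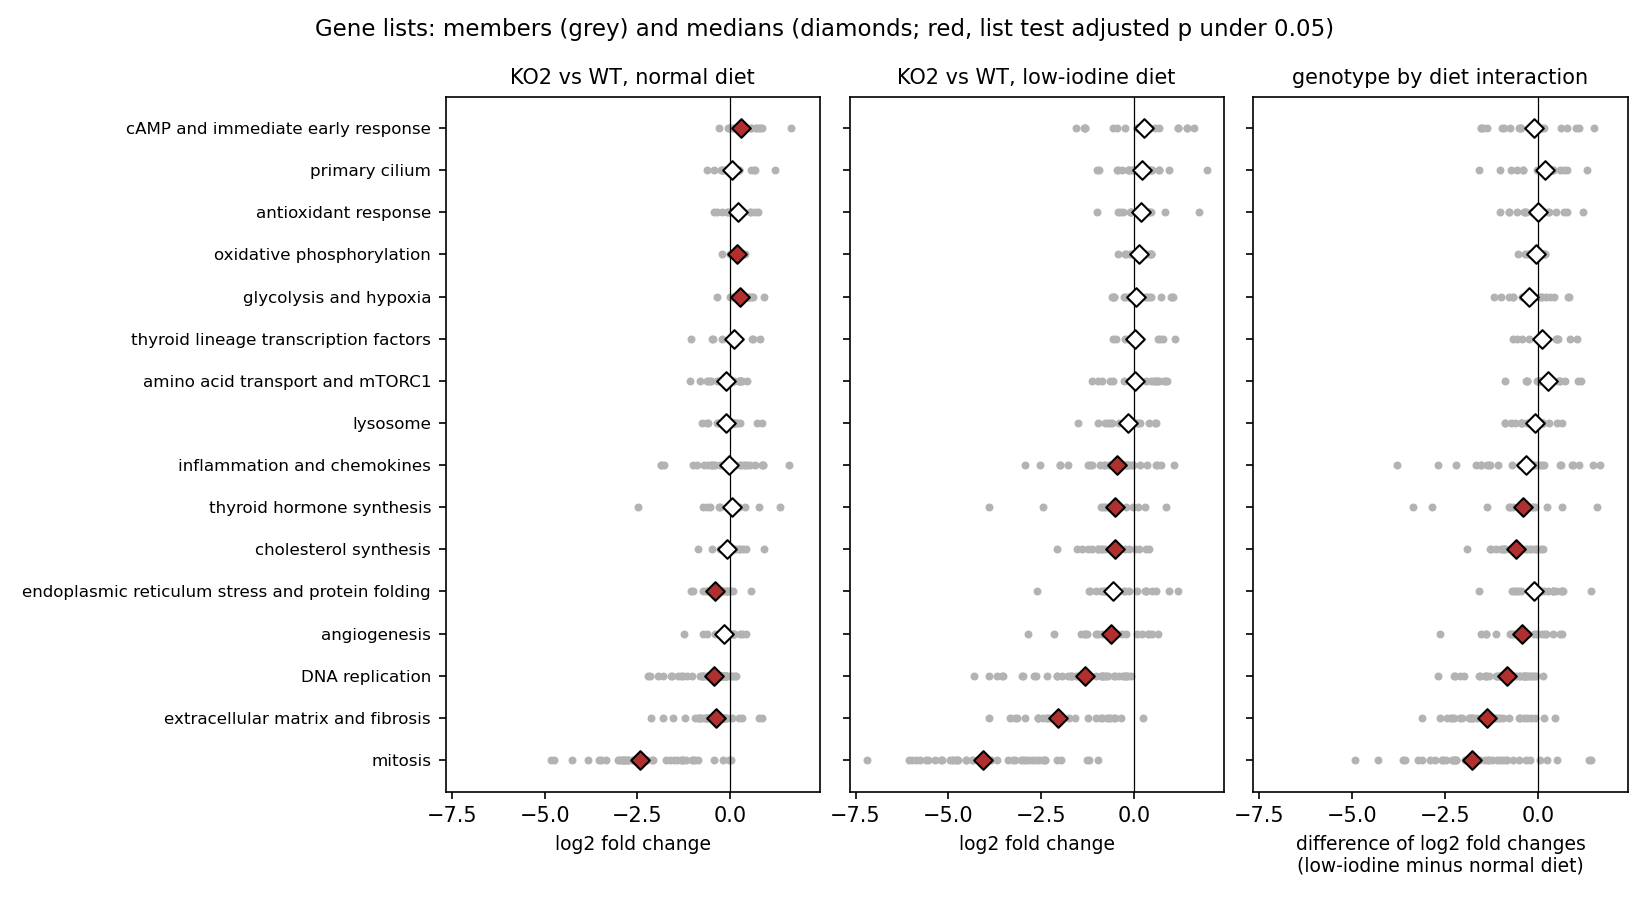
Log2 fold change of each measured member (grey) and the median (diamond) of the 16 pathway lists, for KO2 against WT on each diet and for the difference between diets. Red diamonds passed camera's list test at an adjusted p under 0.05. The mitosis list lay lowest, at −2.44 and −4.07, and the matrix list at −0.38 and −2.05.

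The genotype effects on the diets overlapped. Of 92 genes higher in KO2 on the normal diet, 50 were also called higher on the low-iodine diet, where independent lists would share 7.18 (odds ratio 14.5, two-sided Fisher's exact test over genes p = 2.09e-31). Of 161 lower genes 110 were called lower on both, against 11.5 for independent lists (odds ratio 30.5, exact p = 1.26e-87), and 0 genes were called in opposite directions. Without scaling the shared counts were 8 higher and 177 lower. Genes are not independent replicates, so these p-values overstate the evidence. Both contrasts also share 1 estimate of each gene's spread, which can by itself raise the overlap and the odds ratios. The shared higher count was 30, 33 and 25 without normal-diet WT replicates 2, 3 and 5, 31, 19, 125 and 22 without normal-diet KO2 replicates 1, 3, 4 and 5, and 28 and 30 without low-iodine WT replicate 3 and KO2 replicate 3. The shared lower count was 71 and 72 without normal-diet WT replicates 2 and 5 and 67, 59, 236 and 68 without normal-diet KO2 replicates 1, 3, 4 and 5. S100a5 rose on both diets, Nkx2-1 on both, and Nuf2, E2f1, Tk1 and Col1a1 fell on both. Of 24 alternatives, 13 lost the normal-diet call of S100a5, 14 that of Nkx2-1 and 8 that of Col1a1. Over all genes the fold changes of the diets had a Spearman rho of 0.308 and a Pearson r of 0.400 across genes.

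An array set effect cancels in the difference between the genotype effects only where it adds the same log2 amount to both genotypes. Array sets in which a probe responds more or less strongly do not cancel, nor does a genotype effect that differs by sex. The interaction therefore cannot be told apart from these. It passed the threshold for 221 genes, 66 higher and 155 lower (70.1% lower, against 60.0% with median scaling and 89.3% of the calls without scaling). Of these, 204 differed at least 2-fold. Slc5a5 was among them. KO2 thyroids fell short of WT by more on the low-iodine than on the normal diet, with an interaction of −3.37 ± 0.58 (SE, adjusted p = 0.0102, 0.0121 with slide as a block, and 3.19e-04 to 0.0354 over 23 alternatives). The thyroid hormone synthesis list had a median of −0.41 (1 of 16 lower, adjusted p = 0.0221). Its call was lost in 4 of 28 alternatives: with an estimated correlation (adjusted p = 0.120), the replicate block (0.0656) or the thymic epithelium score (0.0961), and without low-iodine WT replicate 1 (0.0537). The lowest adjusted p was 0.00105, and among its members only Slc5a5 passed. The matrix list had 8 of 30 members lower and 0 higher (19 adjusted over the list alone). Its median was −1.37 (adjusted p = 1.76e-16, 4.91e-15 with slide as a block, and 9.30e-04 with an estimated correlation). Its calls included the cross-linking enzyme Lox (−3.12 ± 0.57 SE), Bgn (−1.85 ± 0.32 SE), Col4a1 (−1.75 ± 0.31 SE) and Sparc (−1.33 ± 0.27 SE). Fibroblast markers had a median interaction of 0.00 (adjusted p = 0.918).

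The interaction was negative for the mitosis list, with 10 of 44 members lower (26 adjusted over the list alone). Its median was −1.79 (adjusted p = 1.24e-16, 3.25e-14 with slide as a block, and 0.224 with an estimated correlation). Its calls included Ttk (−4.92 ± 0.81 SE), Cep55 (−4.31 ± 0.86 SE), Cenpa (−3.59 ± 0.73 SE), Cdc20 (−2.77 ± 0.52 SE) and Ect2 (−2.57 ± 0.51 SE). Iqgap3 differed likewise (−4.23 ± 0.97 SE, adjusted p = 0.0415), but was above 0.05 in 16 of 23 alternatives (8.00e-04 to 0.0993), and Cenpa in 5. Ttk was not well above background in a group, so its value is no bound. For DNA replication 4 of 42 members were lower (9 adjusted over the list alone). The median was −0.84 (adjusted p = 4.24e-12, 8.85e-11 with slide as a block, and 0.224 with an estimated correlation). The calls included Tk1 (−2.28 ± 0.41 SE), the reductase Rrm1 (−1.57 ± 0.33 SE, above 0.05 in 6 of 23 alternatives) and Uhrf1 (−2.24 ± 0.52 SE, adjusted p = 0.0477; 0.0714 with slide as a block, and 0.00145 to 0.0986 over 23 alternatives). Angiogenesis (median −0.45, adjusted p = 0.00593, 0.0136 with slide as a block, and 0.412 with an estimated correlation) had Apln (−2.65 ± 0.42 SE) and Tek (−1.41 ± 0.26 SE) as calls. Cholesterol synthesis (−0.60, adjusted p = 1.48e-05, 3.93e-05 with slide as a block, and 0.120 with an estimated correlation) had 0 calls over all genes and 8 adjusted over the list alone. Endothelial markers (−0.70, adjusted p = 0.00413, and 0.689 with an estimated correlation), and pericyte and smooth muscle markers (−0.79, adjusted p = 0.00924, and 0.447) moved with the interaction. So did cartilage markers (−0.73, adjusted p = 0.0463, and 0.630), skeletal muscle markers (−3.94, adjusted p = 0.0107, and 0.693) and C cell markers (1.09, adjusted p = 2.53e-04, and 0.0590). The muscle call was lost without normal-diet WT replicate 4 (0.0685) or KO2 replicate 4 (0.0562), or low-iodine WT replicate 3 (0.101). The cartilage call was lost in 12 of 28 alternatives (0.0238 to 0.630). Among these were the fits without normal-diet WT replicate 1 (0.0763), 2 (0.0674) or 4 (0.0673), normal-diet KO2 replicate 4 (0.105), low-iodine WT replicate 2 (median −0.21, 0.126) and low-iodine KO2 replicate 2 (0.0589) or 3 (0.0709).

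The largest single interactions were Inmt (5.23 ± 0.53 SE, adjusted p = 1.23e-04), the opioid peptide gene Pdyn (3.06 ± 0.49 SE), the uroplakin gene Upk1a (2.81 ± 0.47 SE) and Slpi (2.55 ± 0.57 SE) on the positive side. The kallikreins Klk1b4 (3.07 ± 0.68 SE, adjusted p = 0.0376) and Klk1b3 (2.88 ± 0.66 SE, adjusted p = 0.0409) joined them. Slpi was above 0.05 in 11 of 23 alternatives (0.00265 to 0.488), with a value as low as 0.58. With slide as a block the kallikreins were at 0.0558 (0.0152 to 0.0788 over 23 alternatives) and 0.0604 (0.0113 to 0.0891). On the negative side they were Dcpp2 (−6.18 ± 1.24 SE), Adamts8 (−4.48 ± 0.68 SE) and Tafa3 (−4.31 ± 0.73 SE) besides the cell division genes. A second probe of Upk1a did not follow the first in KO2 against WT on the low-iodine diet, with −0.31 beside 2.76. With slide as a block 242 genes passed, quantile normalization gave 711 and median scaling 85. The count was 130 and 140 without normal-diet WT replicates 3 and 4, 130 without normal-diet KO2 replicate 2, 140, 120 and 136 without low-iodine WT replicates 1, 3 and 4, and 133 without low-iodine KO2 replicate 4.

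**Figure D3:**
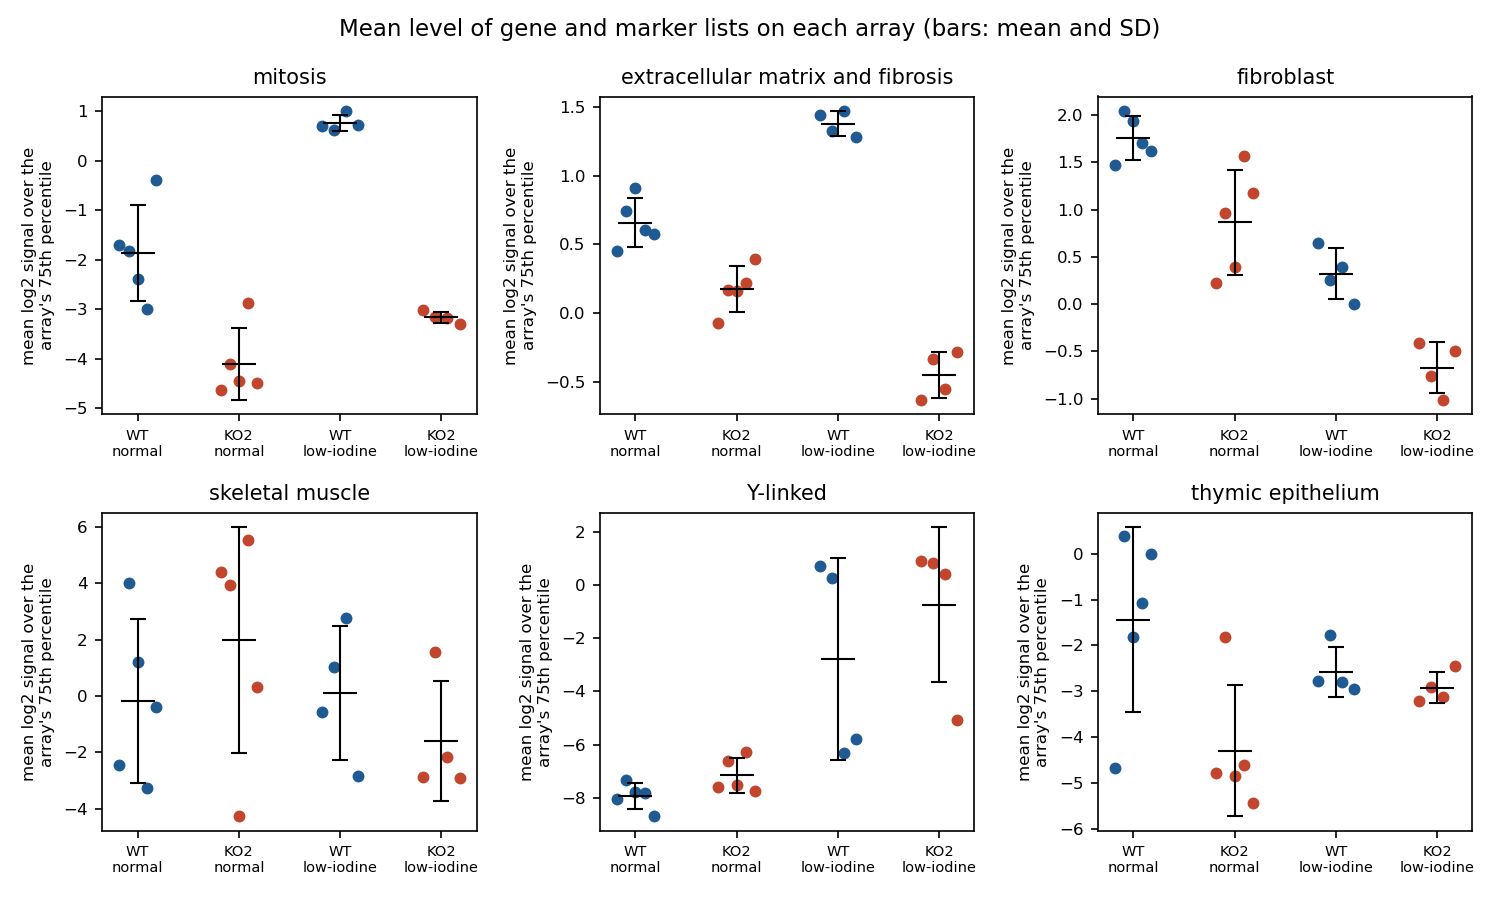
Mean log2 signal relative to the array's 75th percentile of gene and marker lists on each array, by genotype and diet. Points are mice and bars are the mean and SD. Mitosis means were −4.11 in KO2 and −1.86 in WT on the normal diet and −3.16 and 0.77 on the low-iodine diet, while the Y-linked and skeletal muscle lists spread widely within groups.

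Between the diets 13601 of 17929 genes passed the threshold in WT (7064 higher and 6537 lower on low iodine) and 13330 in KO2 (6730 and 6600), and 11971 were shared with the same sign. In WT 48.1% of calls were lower, against 69.3% with median scaling. In KO2 49.5% were, against 68.5% with median scaling and 60.9% without scaling. Slc5a5 lay at −0.77 ± 0.87 (SD, n = 5) in WT on the normal diet and 4.01 ± 0.26 (SD, n = 4) on low iodine, and Tg at 8.64 ± 0.15 (SD, n = 5) and 6.67 ± 0.26 (SD, n = 4). Mitosis genes were higher on low iodine in WT (median 2.42, adjusted p = 4.23e-05, and 0.746 with an estimated correlation), with 38 of 44 higher and 1, Bub1, lower. Examples were Anln (6.33 ± 0.50 SE), Ndc80 (4.73 ± 0.38 SE) and Ttk, which was well above background on 1 of 5 WT normal-diet arrays, so that its fitted difference (7.24 ± 0.57 SE) rests on dim values. The same list had a median of 0.84 in KO2 (17 of 44 higher and 5 lower, adjusted p = 0.290). Oxidative phosphorylation genes were lower in both genotypes (medians −1.58 and −1.69, 21 and 22 of 25 lower). The adjusted p was 3.05e-05 and 1.11e-05, or 0.746 and 0.731 with an estimated correlation. They included the ATP synthase genes Atp5b (−2.41 ± 0.14 SE in WT) and Atp5c1 (−2.98 ± 0.15 SE in WT).

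Many of the largest diet differences were alike in both genotypes. The adaptor Sla2 (9.88 ± 0.24 SE in WT and 10.13 ± 0.24 SE in KO2), the myosin Myo1h (9.56 and 8.70), Pp2d1 (9.08 and 9.24) and, in WT, Fbxl22 (8.55) and B3gnt4 (8.49) were higher. Gipc3 (7.86 and 8.24), Dpysl5 (8.23 and 7.85), Stc1 (8.32 and 7.69), Krtap21-1 (6.98 and 7.51) and Eml5 (7.42 and 7.50) were higher too. Rnh1 (−6.43 and −6.81), Tmem160 (−6.27 and −6.29), the granulin precursor gene Grn (−6.11 and −6.39), Olfr446 (−6.45 and −6.25) and Dusp8 (−6.07 and −5.72) were lower. So were Ier5l (−5.88 and −6.37), Tbc1d16 (−5.59 and −6.35) and Mapkapk2 (−5.83 and −6.19). Sla2 was well above background on 2 of 5 normal-diet WT arrays and 1 of 5 in KO2, B3gnt4 on 1 in WT, Krtap21-1 on 1 in KO2, and Ier5l on 1 of 4 low-iodine KO2 arrays, so these differences too rest on dim values. The saliva protein genes Dcpp2 (11.004 ± 0.88 SE), Dcpp3 (9.18 ± 0.96 SE) and Dcpp1 (8.78 ± 0.92 SE) stood among the largest increases in WT. Xist (−6.41 ± 1.66 SE in WT and −5.44 in KO2), Krt5 (−5.93 in WT and −3.76 in KO2) and Inmt (−5.90 ± 0.38 SE in WT and −0.67 in KO2) stood among the largest WT decreases, and the brown fat uncoupling protein gene Ucp1 (−6.86 ± 1.12 SE in KO2 and −5.30 in WT) among those in KO2. Y-linked markers were higher on low iodine in both genotypes (4 of 4 genes, medians 5.47 and 6.42) and brown adipose markers had medians of −2.79 and −2.67. Neither list passed its test (adjusted p = 0.544 in WT and 0.555 in KO2 for each). Each diet had its own slides, scanner and software release, so diet and array set cannot be told apart and these differences cannot be read as effects of the diet.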

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

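The test of fibroblast markers in this part was chosen only after its result was seen, and the others were written down first. The first pattern weighed is the lower level of mitosis genes in KO2 thyroids on the normal diet, a difference of −2.25 in the mean log2 level of the list. With the thymus and T cell score and the thymic epithelium score of each array as covariates the difference was −2.10 (SE 0.51, 95% interval −3.35 to −0.84). With the skeletal muscle score as a covariate it was −2.43 (SE 0.57, 95% interval −3.79 to −1.07). The muscle score thus moved the difference away from 0, and the thymus scores moved it a little towards 0. Both intervals exclude 0, so neither covariate took the difference away. Both also reach above −1.13, the bound set for excluding either source. A part played by thymus RNA or by a different share of muscle therefore cannot be excluded, or told apart from an effect of the genotype in this list. Psmb11, Prss16 and Ccl25, abundant in thymic epithelium, lay at 2.65, 2.08 and 4.28 in WT replicate 2, at −4.78, −1.56 and −0.65 in WT replicate 1 and at −4.95, −2.96 and −1.12 in KO2 replicate 1. The mean level of the mitosis list on these arrays was −1.82, −1.71 and −4.63. It was highest in WT replicate 5 (−0.39), which carried thymocyte genes. KO2 replicate 2, which carried them too, lay at −4.11. KO2 replicate 4, with a thymic epithelium score of −4.61, had the highest KO2 level (−2.86). Mitosis and thymus levels thus did not move together on every array.

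The second pattern is the matrix list, lower in KO2 by more on the low-iodine diet than on the normal diet. For a wider signal range on the low-iodine arrays, the bound set was a spread at least 2.66 times that of the normal-diet arrays. The ratio of the list medians is 5.32. The widest low-iodine array over the narrowest normal-diet array gave 0.854. The standard deviation of log2 signal across genes was 2.20 to 2.97 on low-iodine arrays and 3.48 to 3.77 on normal-diet arrays, so the range was narrower, not wider. With normal-diet spreads this wide, the bound could hardly be reached. A spread over all genes does not show how strongly the matrix probes respond, so that stays open. The interaction of the mean matrix score was −1.33 with the Y-linked score as a covariate (SE 0.15, 95% interval −1.66 to −0.99) and −1.34 without. This argues against a sex effect that is alike in both genotypes. Only low-iodine arrays had high Y-linked scores, so this fit cannot test a genotype effect that differs by sex, which stays open. Fewer fibroblasts in KO2 thyroids on the low-iodine diet would need a median interaction of the fibroblast markers at or below −0.68. It was 7.47e-04 over members that ran from −1.61 to 1.21 (SD 0.97), a spread that reaches that bound, so this source cannot be told apart and stays open, as does the hypothesis that KO2 thyroids may mount less of a matrix response to low iodine.

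The third pattern is that most genes differed between the diets in both genotypes. Among genes with several probes past the threshold in WT, 35.5% (1557 of 4392) had probes that moved in opposite directions, against 3.16% (15 of 474) for KO2 against WT on the low-iodine diet. The share was 37.8% for the diets in KO2. Array sets that read single probes differently are therefore a likely source of part of these differences, and an effect of the diet, or of sex, stays open because diet, slides, scanner and software release changed together.

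Other splits of the same arrays test whether chance can give such counts. For KO2 against WT on the normal diet, 1 of 100 splits drawn from 126 gave as many genes, the real one with 253, and the highest other gave 127. With low iodine this was 1 of 35, with 2683 and 19. These shares are the lowest that 100 and 35 splits can give. A wrong split also adds the genotype difference to the spread, which lowers its count, so these shares do not exclude chance. For the interaction 4 of 100 splits drawn from 8820 gave as many as the real 221, and the highest other gave 924, several times the real count. All 8 low-iodine arrays had the opposite genotype label in that split, and 4 normal-diet arrays were changed. The structure of the samples it holds is thus the low-iodine genotype difference, turned round. A split of this kind can exceed the real count and is not free of a genotype effect, so chance is not excluded for the interaction. For the diets, 1 of 100 splits drawn from 126 gave as many genes in WT (13601, highest other 11708) and 1 of 100 in KO2 (13330, highest other 11364), with the same limits. The highest other split exchanged 4 normal-diet and 4 low-iodine arrays in each genotype and so nearly mirrors the real one.

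Single arrays stood far from the others of their group in 35 of the 494 groups of values tested, where chance gives about 1 in 20, or 24.7. Median signal was 45.0 in normal-diet KO2 replicate 4 and 191.5 in low-iodine WT replicate 2, whose negative control signal was 61.0. Scores that stood apart on the normal diet were cholesterol synthesis in WT replicate 1 (−0.0606), lysosome in KO2 replicate 4 (3.54), parathyroid in KO2 replicate 3 (−1.78), thymus and T cell in WT replicate 5 (0.54) and Xist in KO2 replicate 5 (−5.64). With low iodine they were cAMP response (0.36) and cholesterol synthesis (−0.16) in KO2 replicate 3, parathyroid in KO2 replicate 1 (−0.26) and skeletal muscle in KO2 replicate 2 (1.58). Macrophage in WT replicate 4 (−0.59) and the Y-linked genes in KO2 replicate 4 (−5.09) stood apart there too.

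Genes that stood apart on 1 normal-diet array were Mki67 (−0.71), Shcbp1 (−3.62), Cdca3 (−1.76) and Tk1 (0.17) in KO2 replicate 4, Clca1 (−1.09), Mxd3 (−0.78) and Kif11 (−2.60) in WT replicate 5, Ano1 in KO2 replicate 2 (−1.31), Col1a2 in KO2 replicate 1 (1.84) and Dusp1 in WT replicate 3 (0.0252). Those on low iodine were Cyp2b9 (−3.98), Nek2 (0.68), Dio1 (4.33), E2f8 (−1.65) and Ndrg1 (1.22) in WT replicate 2, Ccnb1 in WT replicate 3 (−0.39) and Klk1b4 in WT replicate 4 (−4.03). In KO2 they were Dio2 in replicate 2 (−0.66), Isl1 (2.07) and Sparc (2.47) in replicate 1 and Ect2 in replicate 4 (−2.31).

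The interaction passed its threshold for the genes given here and 6 lists, with each diet on an array set of its own. Of the genes, Inmt (5.23), Klk1b4 (3.07), Pdyn (3.06), Klk1b3 (2.88), Upk1a (2.81) and Slpi (2.55) had a positive interaction. Dcpp2 (−6.18), Adamts8 (−4.48), Tafa3 (−4.31), Slc5a5 (−3.37), Lox (−3.12), Apln (−2.65), Bgn (−1.85), Col4a1 (−1.75), Tek (−1.41) and Sparc (−1.33) had a negative one. So did the cell cycle genes Ttk (−4.92), Cep55 (−4.31), Iqgap3 (−4.23), Cenpa (−3.59), Cdc20 (−2.77), Ect2 (−2.57), Tk1 (−2.28), Uhrf1 (−2.24) and Rrm1 (−1.57). The list medians were −1.79 for mitosis, −1.37 for the matrix, −0.84 for DNA replication, −0.60 for cholesterol synthesis, −0.45 for angiogenesis and −0.41 for thyroid hormone synthesis. With an estimated correlation the matrix list passed (adjusted p = 9.30e-04) and the other 5 did not (0.120 to 0.412). Of the genes above, Uhrf1 lost its call in 19 of 23 alternatives, Iqgap3 in 16, Klk1b3 in 14, Klk1b4 in 13 and Slpi in 11.

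Among 9806 probes without a gene name, which the comparisons leave out, 5 passed the threshold for KO2 against WT on the normal diet, 171 on the low-iodine diet and 1 for the interaction.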

How the results depend on the processing

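The muscle and thymus scores as covariates, the fits without 2 arrays that carry thymocyte genes, and the fits of 1 diet alone for lists and named genes were chosen only after the data were seen. No named gene or pathway list past its threshold changed direction under an alternative, but the balance of calls turned round. Of the marker lists past their test, 1 changed direction: the thymus and T cell list on the normal diet, with the thymic epithelium score (median 0.23, adjusted p = 0.696), for which the cause was not tested. The muscle or thymus score was not used as a covariate for its own list. Lower genes were 47.9% of the calls on the low-iodine diet and 45.0% to 86.5% over its alternatives, with 255 higher and 1637 lower without scaling and 711 and 965 with the arrays of that diet alone. For the diets in WT this was 48.1%, and 41.4% to 69.3% (4271 higher and 9645 lower with median scaling), and in KO2 49.5%, and 43.5% to 68.5%. On the normal diet, where 63.6% were lower, the calls were 3 higher and 0 lower with that diet's arrays alone and 11 and 4 with the thymic epithelium score. The fit of that diet's arrays alone has the same fold changes. All 253 calls had an unadjusted limma p under 0.05 in it, so its 3 calls show a loss of calls and no change of direction. For the interaction lower genes stayed the larger share (60.0% to 89.3%). For a smaller or larger count the cause was not tested, except that the 2-fold minimum leaves less by construction.

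For KO2 against WT on the normal diet (253 genes), the count was 392 with trend and robust settings, 990 with array weights, 3 with the arrays of that diet alone, 78 with the thymus and T cell score, 15 with the thymic epithelium score, 94 without the 2 thymocyte arrays and 167 with the replicate block. It stayed within 1.5 times under quantile normalization (184), normexp (264), median scaling (205), no scaling (297), no filter on dim probes (229), a stricter filter (274), the mean of a gene's probes (220), the Y-linked score (221), slide as a block (196), the 2-fold minimum (188) and the skeletal muscle score (366). Leaving out 1 array gave 124 to 679: 156 and 145 without WT replicates 2 and 5, and 160, 124, 679 and 141 without KO2 replicates 1, 3, 4 and 5.

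On the low-iodine diet (2683 genes) median scaling gave 1635, the arrays of that diet alone 1676 and the 2-fold minimum 1321, and leaving out 1 array gave 1988 to 2734. For the interaction (221 genes) quantile normalization gave 711, median scaling 85, no scaling 131, trend and robust settings 351, array weights 523, the skeletal muscle score 89 and the fit without the 2 thymocyte arrays 132. Leaving out 1 array gave 120 to 227: 130 and 140 without normal-diet WT replicates 3 and 4, 130 without normal-diet KO2 replicate 2, 140, 120 and 136 without low-iodine WT replicates 1, 3 and 4, and 133 without low-iodine KO2 replicate 4. The diet counts stayed within 1.5 times under every alternative, at 10822 to 14400 over both genotypes. Without scaling the median of all genes moved to −0.11 on the normal diet, −0.29 on the low-iodine diet and −0.15 for the interaction. Median scaling moved it to 0.13 on the low-iodine diet and for the interaction, and to −0.91 and −0.80 for the diets in WT and KO2.

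Of 7 pathway lists past the test on each diet and 6 for the interaction, an estimated correlation left 2, 2 and 1. For the diets, 2 lists in WT and 1 in KO2 became 0 and 0 with an estimated correlation and 12 and 12 with fry, and in KO2 also 0 with quantile normalization and 2 without scaling. Leaving out 1 array gave 4 (without KO2 replicate 4) to 8 lists on the normal diet, and 1 to 2 for the diets in KO2 (2 without normal-diet KO2 replicate 1 or low-iodine KO2 replicate 3). Without scaling the normal-diet lists for endoplasmic reticulum stress and for oxidative phosphorylation did not pass (both adjusted p = 0.0843). The genes shared between the diets (50 higher and 110 lower) were 8 and 177 without scaling and 31 and 63 with the replicate block, and 19 to 125 and 59 to 236 when 1 array was left out. The report names the arrays behind these ranges.

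Of the 48 normal-diet values of genes chosen by the naming rules, 42 kept their side of the threshold with slide as a block, 41 with quantile normalization, 43 without scaling, 42 with normexp, 34 with the replicate block and 17 with the arrays of that diet alone. Of 82 on the low-iodine diet these numbers were 81, 76, 67, 76, 74 and 68. Replicates of 1 number on a diet shared little beyond their group: their residual correlations ran from −0.0378 to 0.322, so no pairing was used. Spots well above background (60.1% to 90.6% of an array) limit the dim genes, for which a group below background gives only a bound.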

Other observations

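The choice of the added lists for thymic epithelium and for genes that escape X inactivation was made only after the data were seen. Several cell type markers moved with the genotype on the low-iodine diet outside lists that passed their test. The neutrophil gene Retnlg rose by 2.19 beside S100a8 and S100a9, the lipase gene Lpl by 1.81, Cpt1b by 1.57 and the macrophage receptor Cd163 by 0.70. The cilia regulator Foxj1 (−2.07), the red cell anion exchanger Slc4a1 (−1.74) and the pericyte gene Rgs5 (−1.22) were lower. In lists that passed, Cnmd (−3.37) and Col2a1 (−2.86) of the cartilage markers were lower, and Scg2 (1.37) of the C cell markers was higher.

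Marker lists that passed no test for KO2 against WT are given here with their medians on the normal and low-iodine diets: submandibular gland −0.15 and 0.15, white adipose 0.31 and 0.75, brown adipose 0.38 and −0.29, B cell −0.05 and −0.07, macrophage −0.29 and −0.60, neutrophil −0.07 and −0.21, Schwann cell −0.28 and 0.14, erythroid 0.21 and −0.56, and Y-linked 0.67 and 1.98. For the neutrophil list the mean (0.09 and 0.65) and the test direction were upward on both diets. On the low-iodine diet the mean and the test direction were also opposite to the median for submandibular gland (−0.75, downward), brown adipose (0.05, upward) and B cell (0.05, upward). Lists that passed a test elsewhere had medians on the normal diet of 0.03 (C cell, mean −0.28), 0.07 (cartilage, mean −0.42), 0.00 (endothelium) and 0.03 (pericyte and smooth muscle). With low iodine these were −0.10 (parathyroid), −1.87 (skeletal muscle), −0.10 (airway epithelium) and 0.04 (squamous and basal epithelium).

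Thymocyte genes were high on 2 normal-diet arrays, with Rag1 at 1.18, Dntt at 5.12 and Cd3d at 2.38 in WT replicate 5 and −2.06, 0.54 and −0.10 in KO2 replicate 2. Cd3d was also at 0.73 in WT replicate 2 and Dntt at 0.33 in WT replicate 1. Leaving out the 2 arrays therefore does not remove all RNA of this kind. Thymic epithelium genes were high on WT replicates 2 (0.39) and 5 (0.01) and low on WT replicate 1 (−4.68) and KO2 replicate 5 (−5.44). On the normal diet Xist lay between 2.11 and 3.29 on 9 arrays and at −5.64 in KO2 replicate 5, where 0 of 4 Y-linked genes were well above background. Against the mean of the other normal-diet KO2 arrays, that array differed by −1.10 for Kdm6a, −0.34 for Eif2s3x, −0.14 for Kdm5c and −0.03 for Ddx3x, genes that escape X inactivation. On the low-iodine diet all 4 Y-linked genes were well above background on WT replicates 1 and 2 and KO2 replicates 1, 2 and 3.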
